A study of Mus musculus with 3 samples.

How the data were processed

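RNA from lower-limb muscle of 3 control and 3 mFoxO1KO mice was measured on 3 Agilent whole-mouse arrays of 2 colours, all on 1 slide and scanned as 1 batch per the file headers. Per the labels, 0.2 µg of total RNA was labelled with a low-input amplification kit, control in Cy3 and knockout in Cy5. The deposited files are the scanner software's output, 1 per array, with 44397 spots each. They hold the median intensity of each spot and of its local background in both channels as scanned, and per the file headers also processed intensity values that Agilent Feature Extraction 11.5.1.1 had corrected for background, spatial trend and dye. The submitters' processing notes name Feature Extraction 9.3.2.1, so the version is not settled. The deposited log ratio is log10 of processed Cy5 over processed Cy3 intensity, and was found to be 0 where both signals had been replaced by a surrogate. Mean spot signals were not in the columns used here, so median signals took the place that the plan had given them.

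Background was corrected with normexp (offset 50) and each array was normalised by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Between 281 and 319 spots per array were left out because the software marked them as non-uniform or as population outliers. The spots of a probe were averaged. A probe was kept if it was well above background in one and the same channel on all 3 arrays, where a probe with several spots needed a share of at least 0.5 of them. Of several probes of a gene the one with the highest mean intensity was used, and probes of a named gene that went another way are given in the text. Of 39429 probes that were not controls, 27508 (69.8%) took a gene symbol by matching the accession, without its version, to a RefSeq table of the GRCm38.p6 assembly. The other 11921 kept the accession of the array's design and are unnamed here. Of the 17460 genes tested, 12995 had a symbol and 4465 did not. The headers name an older mouse build, so no coordinates are given. No reference genome or probe sequence was used here.

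The log2 ratio of knockout over control was tested against 0 with an intercept-only fit in limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The pairing of the channels comes from the shared array. Errors printed after ± are the SD over the 3 arrays. Before the data were examined, 38 gene lists, the rule for named genes and the processing alternatives were fixed. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 38 lists, and again with the correlation estimated from the residuals and with the rotation test fry. With the preset correlation 11 lists passed, 9 upward and 2 downward, while 0 passed with an estimated correlation and 0 with fry. The genes named are the FoxO family, the 12 with the largest rise and the 12 with the largest fall among named genes past the threshold with 1 sign on all arrays, up to 4 members of each list by smallest p, and every member of the FoxO family, atrophy and FoxO1 target lists past the threshold. Genes named outside that rule are said to have been chosen after their values were seen, except Ucp1, a list member that was not tested and that was also chosen so. Where a gene was not well above background on any control array, its ratio is given as a lower bound.

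The fit was tested on simulated ratios for the 17460 genes with an intensity-dependent dye curve and 200 changed genes. At 1.5-fold, 25 of 50 changed genes were recovered, and at 2-fold, 4-fold and 8-fold all 50 of each, with 10 false calls among 185. A simulated shift of 0.3 in the 32 proteasome genes gave an adjusted p of 1.63e-29 with the preset correlation, 0.296 with an estimated correlation and 0.131 with fry, so neither alternative recovered a shift that was present in 3 arrays of independent genes. In 20 simulations without any shift, 13 of 760 list tests passed, 10 of them for the fast-fibre list and 3 for glycolysis. Without the simulated dye curve the count was 1. Because the simulated genes were independent, false calls at the preset correlation among correlated genes were not measured. The estimated correlations of the 11 called lists ranged from -0.165 for neutrophil genes to 0.84 for adipocyte genes, against the preset 0.01.

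The precision is set by the 3 arrays and by the signal over background, with median Cy3 signals of 90.5 to 97 against local backgrounds of 35.5 to 38, and median Cy5 signals of 99 to 102 against 50.5 to 52. Spike-in spots had median Cy3 signals of 67 to 70.5, close to the 64 to 67 of negative control spots, and were not used. Alternatives covered background correction, the software's own processed signals and log ratios, dye and between-array normalisation, the filter, the choice of probe, the variance model, separate-channel fits with and without the array as a block, and each array left out with the gene set kept. An adjustment for the base composition of probe sequences was planned and not run.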

Results

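Lower-limb skeletal muscle of control mice was compared with that of mFoxO1KO mice, in which Foxo1, a transcription factor gene of the forkhead O family, had been deleted inducibly in skeletal muscle. Both genotypes were male C57BL/6 and received doxycycline in the diet (0.625 g/kg) between 8 and 14 weeks of age. There were 3 biological replicates of each genotype, hybridised in pairs to 3 Agilent whole-mouse arrays of 2 colours, with control RNA in the Cy3 channel and knockout RNA in the Cy5 channel each time. No array had the dyes swapped, so dye effects of single probes cannot be separated from genotype in any ratio given here. Between 52% and 55.9% of probes were well above background in the control channel and between 56% and 56.9% in the knockout channel. No spot was saturated. Across the 17460 genes tested, the log2 ratios of array pairs correlated with Pearson's r of 0.51 to 0.54 and Spearman's rho of 0.42 to 0.55, where genes are not independent replicates. The number of arrays limits the precision of all values.

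Foxo1 transcript was lower in the knockout channel of every array. Its brighter probe gave a mean log2 ratio of -2.06 ± 0.49 (SD, n = 3 arrays), or 23.9% of the control level (limma, adjusted p = 0.0278). The individual arrays gave -1.50, -2.42 and -2.27. The second Foxo1 probe gave -1.39 ± 0.61, or 38.1% of control, with -0.70, -1.64 and -1.84 on the arrays, and an adjusted p of 0.0535 when every probe was tested on its own (limma). Of the other family members, Foxo4 had a log2 ratio of -0.09 ± 0.14 (adjusted p = 0.458) and Foxo6 of 0.39 ± 0.20 (adjusted p = 0.0881), neither past the threshold. When adjusted over the 3 measured family members alone, Foxo1 was lower and Foxo6 higher (limma, adjusted p of 0.000392 and 0.0125). The other Foxo4 probe had 0.05. Foxo3 was well above background on only 1 control array and was not tested. Whether either Foxo1 probe lies in the deleted part of the gene is not known here, so the probes check the labels only if they do. Without replicate 2 the Foxo1 ratio was -1.88 and its adjusted p 0.106, within a range of 8.41e-05 to 0.106 over 17 alternatives.

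The comparison of the genotypes asks which transcripts change in muscle in which Foxo1 was targeted. Among named genes past the threshold, the largest fall was that of Dkk3, a secreted glycoprotein of the Dickkopf family, at -2.68 ± 0.30 (SD, n = 3), or 6.39-fold (limma, adjusted p = 0.00934). Htra4, a serine protease gene, fell 4.57-fold, Pfkfb3, which makes fructose 2,6-bisphosphate and so stimulates glycolysis, fell 3.40-fold, and Kcnab1, a potassium channel subunit gene, fell 3.31-fold (adjusted p of 0.0215, 0.0341 and 0.0366). The largest rises among them were those of the metallothionein Mt1, at 2.14 ± 0.35 or 4.41-fold (adjusted p = 0.0134), and of haptoglobin (Hp), a plasma protein that binds haemoglobin, at 1.85 ± 0.11 or 3.61-fold (adjusted p = 0.00934). Ankrd1, a muscle ankyrin repeat protein gene, rose 3.22-fold, Atf3, a stress-induced transcription factor gene, 2.70-fold, and the chemokine gene Cxcl13 2.88-fold.

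**Figure D1:**
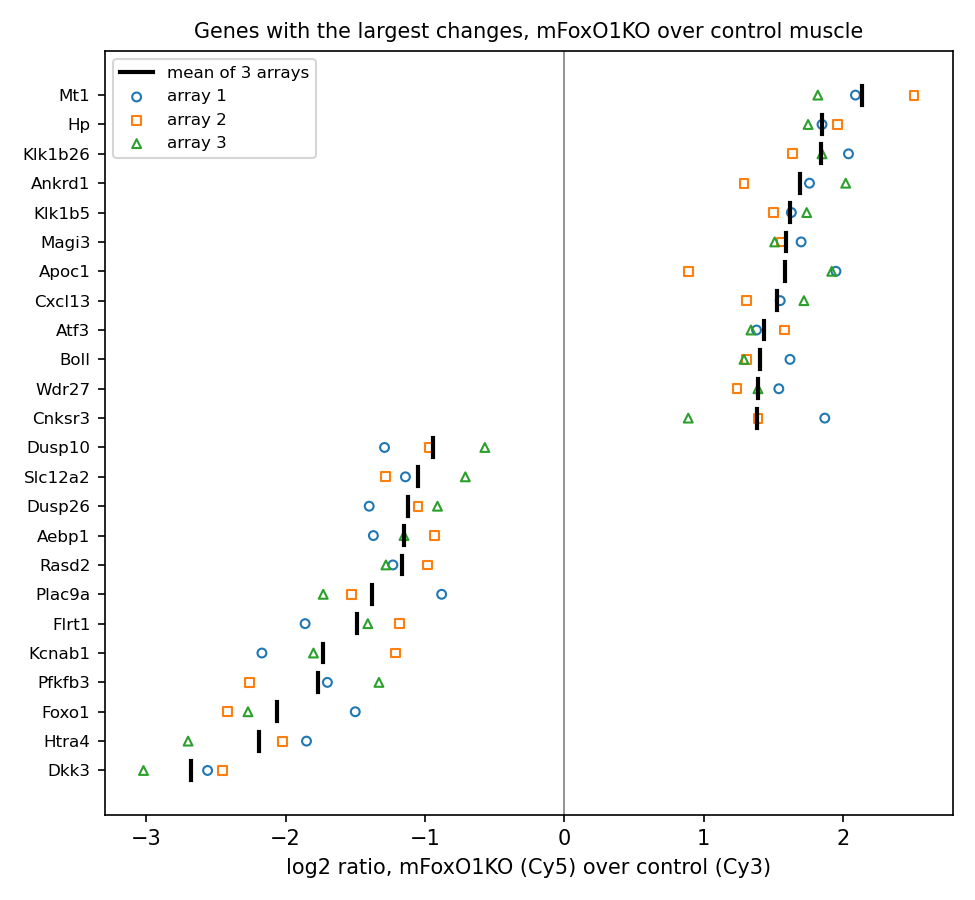
Log2 ratio of mFoxO1KO over control muscle (horizontal axis) for the 12 genes with the largest rise and the 12 with the largest fall among named genes past the threshold; open symbols are the 3 arrays and the black bar is their mean. All arrays of a gene lie on the same side of 0, as the rule for choosing them required, from Mt1 with a mean of 2.14 to Dkk3 with a mean of -2.68.

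The rest of the 12 named genes with the largest rises were the kallikreins Klk1b26 (3.59-fold) and Klk1b5 (3.08-fold), the apolipoprotein gene Apoc1 (3.00-fold), Cnksr3 (2.61-fold), Magi3, Boll and Wdr27. Magi3, Boll and Wdr27 were not well above background on any control array, which leaves lower bounds of at least 3.01-fold, at least 2.63-fold and at least 2.57-fold. The other Magi3 probe had a log2 ratio of 0.03. Such bounds set the knockout mean against the control signal or the lowest signal counted as above background on that array, whichever is higher, and remain open to dye bias. Among the 12 with the largest falls were also Flrt1 (2.80-fold), Plac9a (2.61-fold), the GTP-binding protein gene Rasd2 (2.24-fold), Aebp1 (2.22-fold), the phosphatase genes Dusp26 (2.18-fold) and Dusp10 (1.92-fold), and the sodium-potassium-chloride cotransporter gene Slc12a2 (2.07-fold). The other Flrt1 probes had log2 ratios of 0.01 and -1.02.

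In all, 481 of 17460 genes passed an adjusted p of 0.05 (limma), 359 higher and 122 lower in the knockout, and 354 of them had a gene name (253 higher, 101 lower). All 481 had the same sign on all 3 arrays, which the test favours, against 52.4% of all genes tested. The absolute log2 ratios of the 481 ranged from 0.36 to 2.68. At an unadjusted p under 0.05 there were 4679 genes. A difference of at least 2-fold on every array, a count without a test, was found for 48 genes, 42 higher and 6 lower, of which 45 were among the 481. The count of 481 was lower with fewer arrays and without dim probes. It was 405 without replicate 1, 49 without replicate 2, 157 without replicate 3, 55 when probes had to be above background in both channels, and 9 when only genes above the median intensity were tested. With the array as a block in a fit of the separate channels it was 1649 (1040 higher, 609 lower), and without loess, by median centring only, 1204 (1153 higher, 51 lower).

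Genes listed for muscle wasting under FoxO control did not move together, but the list set no direction for each member. Of 29 measured atrophy genes, 3 rose, none fell and 26 did not pass the test, while 8 rose and 4 fell when adjusted over the list alone. The 3 that rose were Mt1, Ppargc1a, a coactivator of mitochondrial genes (1.35 ± 0.52, adjusted p = 0.0492), and the cell cycle inhibitor gene Cdkn1a (0.83 ± 0.23, adjusted p = 0.0401). Ppargc1a passed in 6 of 17 alternatives. Mt2, a second metallothionein gene, had 2.24 ± 0.95 (limma, adjusted p = 0.0517) and Ctsl, which encodes the lysosomal protease cathepsin L, -0.60 ± 0.28 (adjusted p = 0.0664), neither past the threshold. Chosen after their values were seen, Fbxo32 had -0.72 ± 0.50 (adjusted p = 0.104) and Cebpd -0.87 ± 0.53 (adjusted p = 0.0874). Both were below 0 on every array and, like Ctsl, were among the 4 lower when adjusted over the list alone. The list's median was -0.11, its mean 0.17 and its test direction upward (camera, adjusted p = 0.921), and with median centring only the median was 0.20 and the list passed (adjusted p = 0.0434). Of 27 autophagy and lysosome genes none passed, over all genes or when adjusted over the list alone (median -0.01, camera adjusted p = 0.842).

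The proteasome list shifted downward by a small amount, with a median of -0.07 over 32 genes (camera, adjusted p = 0.0219), but had a median of 0.23 with median centring only, a setting that raised the median of all genes to 0.156. Its adjusted p was 0.725 with an estimated correlation and 0.247 without replicate 2, within a range of 0.00553 to 0.725 over 19 alternatives. No single proteasome gene passed, over all genes or when adjusted over the list alone, and Psme4, a proteasome activator gene, had -0.39 ± 0.13. Metabolic genes bound or controlled by FoxO1 had a median of 0.24 over 18 genes and passed as a list (camera, adjusted p = 0.0395). Their adjusted p was 0.725 with an estimated correlation and 0.0609 without background subtraction, within a range of 2.28e-05 to 0.725 over 19 alternatives. None of the 18 passed over all genes, and 2 were higher when adjusted over the list alone. The lipoprotein lipase gene Lpl had 0.79 ± 0.37, Angptl4, an inhibitor of that enzyme, 0.87 ± 0.55, and the insulin receptor substrate gene Irs2 0.92 ± 0.67. Of the 18 means, 14 were above 0 and 4 below. Of 2 genes chosen after their values were seen, Pdk4 had -0.42 ± 0.33 (limma, adjusted p = 0.138) and was below 0 on every array. The other, Pck1, had 3.47, 0.01 and 2.30 on the 3 arrays (adjusted p = 0.153). In insulin and IGF signalling, 1 of 21 genes passed over all genes, and 1 was higher and 3 were lower when adjusted over the list alone. The gene that fell was Tbc1d4, which encodes an Akt substrate that governs glucose transporter traffic (-0.65 ± 0.16, limma adjusted p = 0.0413), and the list as a whole did not pass (median 0.05, camera adjusted p = 0.573).

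Fatty acid oxidation genes shifted upward, with 32 of 34 mean ratios above 0 and a median of 0.20 (camera, adjusted p = 6.89e-06, and adjusted p = 0.725 with an estimated correlation). Ppara, the nuclear receptor gene that drives fatty acid catabolism, rose by 0.87 ± 0.09 (1.82-fold, limma adjusted p = 0.0179), and the lipid droplet gene Plin5 by 0.66 ± 0.21 (adjusted p = 0.0491). The other 32 did not pass over all genes, and 15 rose when adjusted over the list alone. The list also holds genes of lipid storage and uptake, and its largest ratios were those of Plin2 (1.33), Angptl4 (0.87), Ppara and Lpl (0.79). The acyl-CoA dehydrogenase genes Acadm, Acadvl, Acadl and Acads had only 0.05, 0.06, 0.07 and 0.285, and Cpt1b and Cpt2 had 0.09 and 0.28. The shift is therefore not one of the oxidation enzymes alike. Lipogenesis genes had a median of 0.33 over 18 genes (camera, adjusted p = 0.000377, and adjusted p = 0.725 with an estimated correlation), with 3 past the threshold and 10 when adjusted over the list alone. The 3 were Dgat2, which completes triglyceride synthesis (1.02 ± 0.40), the acetyl-CoA carboxylase gene Acaca (0.66 ± 0.15) and the fatty acid elongase gene Elovl5 (0.46 ± 0.11). Cholesterol synthesis genes had a median of 0.06 over 17 genes and none passed, over all genes or when adjusted over the list alone (camera, adjusted p = 0.426).

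Adipocyte markers were higher in the knockout channel by different amounts on the 3 arrays, and both lipid lists had their highest medians on the same array. The median of 13 adipocyte genes was 2.07 on array 1, 0.22 on array 2 and 1.19 on array 3. On the same arrays that of fatty acid oxidation genes was 0.28, 0.09 and 0.19, that of lipogenesis genes 0.47, 0.20 and 0.34, and that of FoxO1 metabolic targets 0.19, 0.06 and 0.20. The adipocyte list passed as a whole with a median of 1.21 (camera, adjusted p = 0.00218, and adjusted p = 0.725 with an estimated correlation). No adipocyte gene rose past the threshold over all genes, with 9 higher and 1 lower when adjusted over the list alone. The lipid droplet genes Cidea and Cidec had 3.12 ± 1.55 and 2.00 ± 1.11. Car3, a carbonic anhydrase gene of fat and of slow muscle fibres, was the exception and fell by 0.81 ± 0.07 (SD, n = 3, limma adjusted p = 0.0188). Ucp1, the uncoupling protein gene of brown fat, had ratios of 2.53 and 2.12 on arrays 1 and 3 and was not above background in either channel of array 2, so it was not tested. Without the genes that are also on the adipocyte list, a count added after the data were seen, 10 lists passed in place of 11, the adipocyte list itself being empty. This left 33 fatty acid oxidation genes and all 18 lipogenesis genes, so it could change little. Genes with a similar array pattern stayed in, such as Scd1 with 2.88, 0.71 and 1.87. The count therefore does not show that the lipid lists are independent of fat.

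**Figure D2:**
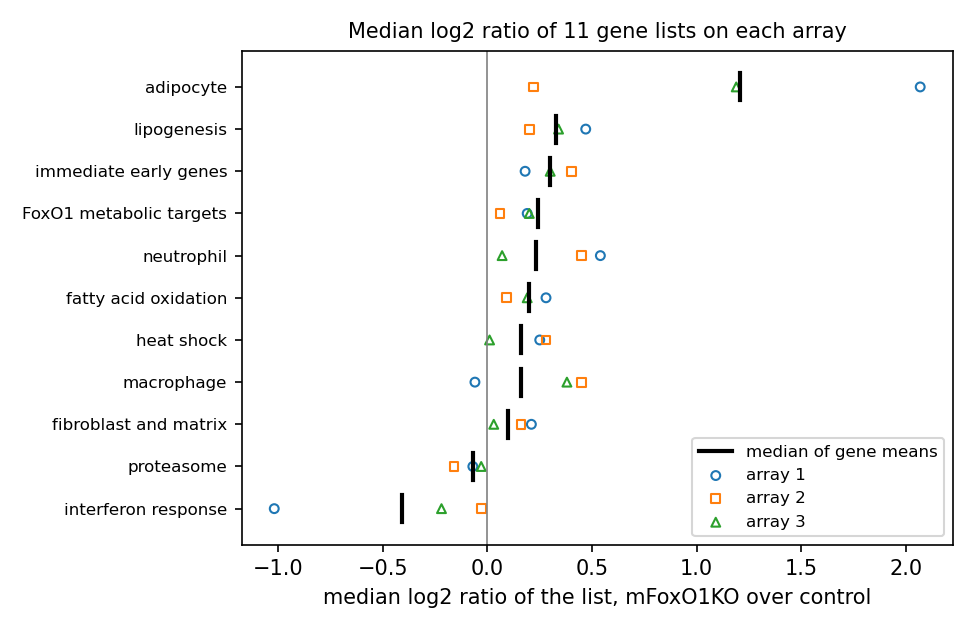
Median log2 ratio of mFoxO1KO over control (horizontal axis) for the 11 gene lists past an adjusted p of 0.05 in camera; open symbols are the medians on the 3 arrays and the black bar is the median of the genes' means. The adipocyte list lies at 2.07, 0.22 and 1.19 and the interferon list at -1.02, -0.03 and -0.22, the widest spreads between arrays of the 11 lists.

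Carbohydrate genes moved in both directions. Of 29 glycolysis and glycogen genes, 4 rose and 1 fell, against 11 and 5 when adjusted over the list alone, and the list did not pass (median 0.17, camera adjusted p = 0.0597). Ppp1r3c, which targets a phosphatase to glycogen, rose by 0.96 ± 0.22, the aldolase gene Aldoa by 0.49 ± 0.04 and the hexokinase gene Hk2 by 0.45 ± 0.03, while Pfkfb3 fell by 1.76 ± 0.46 (SD, n = 3). Respiratory chain genes had a median of 0.08 over 42 genes (camera, adjusted p = 0.0597) and none passed, over all genes or when adjusted over the list alone. With median centring only both lists passed, glycolysis and glycogen with a median of 0.49 (adjusted p = 9.82e-06) and the respiratory chain with 0.43 (adjusted p = 1.87e-08). With the deposited log ratios their medians were 0.06 (adjusted p = 0.454) and 0.00 (adjusted p = 0.609). Alas1, which encodes the first enzyme of haem synthesis, rose by 0.63 ± 0.21. It was the 1 that passed of 24 genes of amino acid catabolism, against 3 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.84). In polyamine synthesis 1 of 11 genes fell, also when adjusted over the list alone. It was Odc1, the ornithine decarboxylase gene (-0.93 ± 0.18, limma adjusted p = 0.0278), and the list did not pass (camera, adjusted p = 0.426).

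Few genes of fibre type and myogenesis passed the test. Among 16 slow-fibre genes, Ankrd2 rose by 1.21 ± 0.27 and the myoglobin gene Mb by 0.57 ± 0.14, against 3 higher when adjusted over the list alone (camera, adjusted p = 0.19). Among 16 fast-fibre genes, Myl1, a myosin light chain gene, fell by 0.60 ± 0.10, against 1 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 0.438, and adjusted p = 0.0434 upward with median centring only). Of 19 genes of myogenesis and regeneration, the muscle transcription factor gene Mef2a rose by 0.63 ± 0.15 and the cardiac actin gene Actc1 fell by 0.84 ± 0.23. The other Mef2a probe had -0.07, and 3 genes were higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.426). Of 20 genes of denervation and the neuromuscular junction, the receptor genes Musk (0.96 ± 0.34) and Lrp4 (0.52 ± 0.14) rose, against 5 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.19).

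Immediate early genes, which respond within minutes to stimulation, shifted upward with a median of 0.30 over 22 genes (camera, adjusted p = 0.0007, and adjusted p = 0.725 with an estimated correlation). Atf3 (1.43 ± 0.13), Fos (2.14-fold) and Nr4a1 (0.76 ± 0.23) rose, and 10 were higher when adjusted over the list alone. Heat shock genes had a median of 0.16 over 15 genes (camera, adjusted p = 0.0427) with none past the threshold and 4 higher when adjusted over the list alone. Their adjusted p was 0.725 with an estimated correlation, 0.0746 without replicate 1 and 0.244 without replicate 2, within a range of 0.000177 to 0.725 over 19 alternatives. In the glucocorticoid list 3 of 17 genes rose, Mt1, Cdkn1a and the lipocalin gene Lcn2 (1.14 ± 0.38), against 7 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 0.218). Of 23 oxidative stress genes Mt1 rose and the plasma glutathione peroxidase gene Gpx3 fell by 0.47 ± 0.05, against 5 higher and 4 lower when adjusted over the list alone (camera, adjusted p = 0.571). None of 25 ATF4 and unfolded protein response genes passed, with 5 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 0.273). The glutathione-degrading enzyme gene Chac1 had -1.03 ± 0.46.

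Interferon response genes shifted downward as a list, with a median of -0.41 over 21 genes (camera, adjusted p = 0.00159, and adjusted p = 0.725 with an estimated correlation). No single member passed, over all genes or when adjusted over the list alone, and Ifit1 had -0.86 ± 0.63 and Isg15 -0.59 ± 0.48. The median was -1.02 on array 1, -0.03 on array 2 and -0.22 on array 3, and -0.15 without replicate 1. There the list passed at the preset correlation (camera, adjusted p = 0.0336, within a range of 3.39e-12 to 0.725 over 19 alternatives) but not with an estimated one (adjusted p = 0.884).

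Macrophage genes had a median of 0.16 over 13 genes (camera, adjusted p = 0.0453, and adjusted p = 0.725 with an estimated correlation). Cd14, a co-receptor for endotoxin, rose by 0.95 ± 0.31, and 2 were higher when adjusted over the list alone. The macrophage median was -0.06, 0.45 and 0.38 on the 3 arrays, and 0.36 without replicate 1 (adjusted p = 1.82e-06). The list did not pass without replicate 2 or 3 (adjusted p = 0.463 and 0.147), within a range of 1.82e-06 to 0.725 over 19 alternatives. Neutrophil genes had a median of 0.23 over 5 genes and fibroblast and matrix genes 0.10 over 25 (camera, adjusted p = 0.0453 each, and adjusted p = 0.725 each with an estimated correlation). Lcn2 and the collagen cross-linking enzyme gene Lox (0.47 ± 0.13) were the members that rose, with 2 and 1 higher when adjusted over the list alone. The neutrophil median was 1.33 with the software's processed signals and 1.29 with the deposited log ratios, within a range of 0.16 to 1.33 over 19 alternatives. The neutrophil list did not pass without replicate 1 (adjusted p = 0.0746, range 0.0033 to 0.725), nor the matrix list without replicate 1 or 2 (adjusted p = 0.403 and 0.118, range 0.00212 to 0.725).

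Among 7 tendon genes Prg4, which encodes the lubricant lubricin, rose by 0.79 ± 0.20. It was also the 1 higher gene when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.394). The endothelial list had a median of 0.14 over 16 genes (camera, adjusted p = 0.119, 1 higher when adjusted over the list alone). Pericyte and smooth muscle genes had a median of -0.01 over 12 genes with an upward test direction (adjusted p = 0.949), and Schwann cell and nerve genes 0.09 over 13 (adjusted p = 0.426), each with 1 gene higher when adjusted over the list alone. Skin epithelium had a median of 0.18 over 4 genes (adjusted p = 0.394), lymphocytes -0.01 over 7 (adjusted p = 0.949) and erythroid cells 0.23 over 9 (adjusted p = 0.426). The erythroid median was 0.88, 0.02 and -0.24 on the 3 arrays. No gene of the endothelial, pericyte, Schwann cell, skin, lymphocyte or erythroid lists passed over all genes. The same held for cell cycle genes (median -0.10 over 18, camera adjusted p = 0.108) and angiogenic factors (0.12 over 13, adjusted p = 0.359, 3 higher when adjusted over the list alone). It held too for circadian clock genes (-0.02 over 16 with a mean of 0.01, adjusted p = 0.44) and ribosome and translation genes (0.00 over 27 with an upward test direction, adjusted p = 0.949).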

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

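The test on genes above the median intensity and the lists without adipocyte genes were chosen after the data were seen. Foxo1 kept its direction in all 17 alternatives and passed in 15 (limma), with log2 ratios from -2.35 to -1.73. It missed the threshold among genes above the median intensity (-2.06, adjusted p = 0.0517) and without replicate 2 (0.106), and leaving out each replicate gave -2.35 to -1.88. The count of 481 genes was 186 with normexp offset 10, 212 with the deposited log ratios, 1204 with median centring only, 830 with scaling between arrays, 746 without a filter, 55 with probes above background in both channels and 9 among genes above the median intensity. Separate channels gave 1649 with the replicate block and 216 with no replicate block, and leaving out each replicate gave 49 to 405. The share of calls that were higher, 74.6% in the reported fit, was 95.8% with median centring and 63.1% with the block. All 55 and all 9 were among the 481, as were 35 of the 49 and 451 of the 1649. The count of 48 genes at 2-fold on every array was 82 with offset 10, 251 with processed signals, 240 with the deposited log ratios, 31 above background in both channels, and 66 to 111 with each replicate left out. Of 38 lists 11 passed, against 6 without background subtraction, 19 with median centring, 0 with an estimated correlation, 0 with fry, and 8 to 14 with each replicate left out. With median centring only, the proteasome median turned to 0.23 and the fast-fibre median to 0.34 (adjusted p = 0.0434), as the median of all genes moved to 0.156. The medians of atrophy (0.20), autophagy (0.22), pericyte (0.15), lymphocyte (0.13), circadian (0.16) and polyamine genes (0.21) turned there too. Without replicate 1 the erythroid median turned from 0.23 to -0.11, and some other medians near 0 turned there or under other settings. Of 51 other named genes past the threshold none changed sign, 7 passed in every alternative run (Hp, Klk1b26, Klk1b5, Wdr27, Atf3, Rasd2 and Dkk3), and 14, 38 and 23 did not pass without replicate 1, 2 and 3. Hp, Rasd2 and Dkk3 were tested in 17 alternatives, Klk1b26, Klk1b5 and Atf3 in 16 and Wdr27 in 15. Klk1b26, Klk1b5, Atf3 and Wdr27 were too dim to be tested above the median intensity. Wdr27 was not tested with probes above background in both channels either. For these genes the checks on dim probes were therefore partly not run. The highest adjusted p of each of the 7 was 0.0499 (limma), just under the threshold. Above the median intensity 35 of the 51 were tested and 31 did not pass. With probes above background in both channels 49 were tested and 32 did not pass. The fewest passes were 6 of 17 alternatives for Ppargc1a, Dgat2 and Alas1 and 6 of 16 for Lox. The smaller counts without a replicate go with fewer arrays tested. Those fits used the same number of arrays, yet gave 405, 49 and 157 calls without replicate 1, 2 and 3. The number of arrays therefore does not explain the spread among them. Of the 481 genes, 263 were still tested above the median intensity and 398 with probes above background in both channels. The counts of 9 and 55 are therefore not explained by genes left out alone. For these and the other changes the cause was not tested. The adjustment for base composition was not run. Signal over background limits the dim genes: 68 called genes were above background on no control array.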

Other observations

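All genes and groups of the first 2 paragraphs, the MHC class II genes, and the tests of dye bias, of background correction alone, of adipose tissue in the samples of arrays 1 and 3 and of immune cells, were chosen after the result was seen. Of 7 metal-binding and acute-phase genes picked for their values, the mean log2 ratios were 0.95 to 2.24. Past the threshold were Mt1, Hp, Lcn2, Cd14 and Slc39a14, a zinc and iron importer gene (1.20 ± 0.34, SD, n = 3, limma adjusted p = 0.0390), and not past it were Mt2 and S100a9, a neutrophil protein gene (1.28 ± 0.79, adjusted p = 0.0874). The strain-responsive genes Ankrd1, Ankrd2 and Rrad (0.78 ± 0.21, adjusted p = 0.0396) rose, while Csrp3 had 0.76 ± 0.61 (adjusted p = 0.132).

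Major urinary protein genes, whose copies are nearly identical so that probes can cross-hybridise, had mean log2 ratios of 0.75 to 1.90 over 8 genes, all above 0 on each array and none past the threshold (Mup18 had 1.52 ± 0.67, limma adjusted p = 0.0551). The glandular kallikreins, also close copies, had 0.34 to 1.84 over 5 genes, of which Klk1b26, Klk1b5, Klk1b16 (1.23 ± 0.14, adjusted p = 0.0121) and Klk1b22 (0.85 ± 0.10, adjusted p = 0.0202) rose. The interferon-induced GTPase genes Tgtp2 and Gbp4 had -1.69 ± 1.04 and -1.25 ± 0.69 (adjusted p of 0.0858 and 0.0747), with their lowest values, -2.88 and -2.04, on array 1.

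More genes were called higher than lower in the knockout channel, 359 against 122, and the real arrangement of the channels gave 481 calls while the highest of the other 3 that part every array's pair gave 0, the real one being 1 of 4 splits, too few for a share under 0.05. Dye bias of dim probes may account for part of this, but was not separated from the filter. The share of calls that were higher was 83.9% below the median intensity and 66.9% above it (Fisher's exact test, two-sided p = 2.24e-05). Receptor genes of smell, pheromone and taste are not typical of muscle. Of 62 dim receptor genes 9 were called higher, against 174 of 8668 other dim genes (Fisher's exact test, p = 5e-06). The filter also kept dim probes above background in the knockout channel alone, a choice that favours higher ratios. Of the 62 receptor genes, 19 were above background on no control array, as were 68 of the 481 called genes. Neither contrast can therefore tell dye bias from the filter. Background correction alone is argued against for the calls from these 3 arrays. The share was 78.7% without background subtraction (exact 95% interval over called genes 74.6% to 82.4%) and 78.8% with the software's processed signals (75.6% to 81.7%), against 74.6% in the reported fit. The share was 74.1% without the filter on dim probes, but 67.3% with probes above background in both channels (53.3% to 79.3%), an interval that reaches below the limit of 60% and was required only after the value was seen, so the filter stays open. These intervals and the Fisher p-values treat genes of the same 3 arrays as independent, so they do not measure the spread between animals. Dye bias of bright probes cannot be told apart from the genotype, because no array had the dyes swapped, and an effect of the deletion stays open as untested.

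Adipocyte markers followed the array, with 12 of 13 higher on both arrays 1 and 3 than on array 2, and the exception was Car3, which is abundant in fat and fell. Adipose tissue in those knockout samples is a candidate source, and a change in the muscle itself was not tested. Extrapolated to an adipocyte ratio of 0 by a line through the 3 arrays, fatty acid oxidation genes outside the adipocyte list kept a median of 0.10 (interval over 33 genes 0.06 to 0.18) of 0.19 observed, and lipogenesis genes 0.19 (0.02 to 0.30, 18 genes) of 0.33. Both intervals held 50% of the observed median, the value set as the limit, so whether fat makes up most of either shift cannot be told apart with 3 arrays. Of the 15 adipocyte genes listed, Lipe is also on the fatty acid oxidation list and Fabp4 on that of FoxO1 targets.

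Interferon response genes were lowest on array 1, where 20 of 21 had ratios below 0 and the median was -1.02. The ratio of 1 pair does not tell a lower knockout sample from a higher control sample. A loss of immune cells from that knockout sample would need their markers to fall by a similar amount, and the 20 measured macrophage and lymphocyte markers had a median of -0.09 there (interval over genes -0.25 to 0.01), above the -0.51 set as the limit. Some of the 20 were dim, such as Jchain, well above background on 1 control array. Ratios of dim genes depend on the background correction, as for the neutrophil median of 0.23, or 1.33 with processed signals. The median of -0.09 is therefore a weak bound on a loss of cells from the knockout sample of array 1. The MHC class II genes H2-Ab1, Cd74, H2-Eb1 and H2-Aa, of which all but H2-Eb1 are among the 20, had -1.02, -0.81, -0.81 and -0.59 on that array, so a loss of cells rich in them stays open, and a change in the muscle itself was not tested. Without array 1 the list median was -0.15 and the call held at the preset correlation (camera, adjusted p = 0.0336) but not with an estimated one (adjusted p = 0.884), so a difference of 1 array only stays open. The plan took the first of these as enough to exclude it, which was wrong because the estimated correlation of the list was 0.708 against the preset 0.01.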
